A study of Homo sapiens with 48 samples.

How the data were processed

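RNA was measured by oligo-dT mRNA sequencing in 48 libraries of the human KOLF2.2J line, 36 from trophoblast cultures and 12 from cortical organoids, in 16 groups of 3. Knockout libraries came from 3 clones each and wild-type libraries from 3 cultures of the parental line, per the labels. The trophoblast libraries form 3 sets (A, B and C), each with its own wild type, and the organoid libraries form a day 8 and a day 22 set. Replicates were numbered in the order of deposit. The series title counts 10 genes, while the sample labels give 11, and all 11 were analysed.

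The authors name STAR, Salmon and featureCounts with the GRCh38 build, without versions, order, parameters, annotation release or strand setting. The gene table used here was deposited as featureCounts read counts, 38592 genes by 48 libraries, with no normalization found in the values. The authors also deposited gene-level and transcript-level Salmon estimated counts (226049 transcripts), and a table of read-assignment counts per library (unmapped, multimapping, in no gene, ambiguous). Rounded copies and transcripts-per-million tables were not used, since they derive from the estimated counts. Of the genes, 38568 had a symbol. Positions and transcript names came from GENCODE release 29, which held 76.9% of the transcripts and 90.7% of the transcript counts; the rest were left out of the usage tests.

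Total counts per library ran from 18 M to 27.9 M in trophoblast and from 29.4 M to 37.8 M in organoids. Of the reads, 4.32 to 5.58% and 5.11 to 6.02% were unmapped, 5.48 to 8.41% and 3.97 to 6.37% multimapping, and 3.80 to 4.71% and 3.32 to 5.52% ambiguous, in trophoblast and organoids. Mitochondrial genes took 4.16 to 5.42% and 0.792 to 1.45% of counts, and the 10 most abundant genes 6.26 to 8.12% and 4.10 to 6.12%. Each group pair had 3 against 3 libraries, so the precision of a change is set by the spread between clones or cultures. Floors for genes at 0 were taken as 3 counts over the group, and cover counting error only, since reads without molecular identifiers are not independent molecules.

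Counts were analysed with edgeR 4.0.16 in R 4.3.3. Within each set, genes with low counts were removed with filterByExpr by group, libraries were scaled by TMM, and a quasi-likelihood negative binomial model with a mean per group was fitted (glmQLFit and glmQLFTest). Each knockout was compared with the wild type of its set, and knockouts of 1 family were compared directly. Wild-type organoids at day 22 were compared with those at day 8, and the 3 wild-type trophoblast groups with one another by an F test. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. Log values used a prior count of 2. Levels are CPM on TMM-scaled library sizes. Genes changed in common were compared with the number expected from the counts called and with 20 simulations of unchanged groups and their shared controls, in which genes vary independently; the same was done for transcript usage after the data were seen. The covariance of log2 changes was also taken with the wild-type libraries divided between the knockouts, a step added after the data were seen.

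Gene sets were tested over 34 lists of 473 genes, each list with at least 5 tested members, using camera of limma 3.58.1 with a preset inter-gene correlation of 0.01. Camera was repeated with an estimated correlation, and fry was run on the same lists. Set p-values were adjusted over the 249 list tests of the 11 knockout comparisons together, and separately over those of the day contrast. Transcript usage in set B was tested with diffSpliceDGE of edgeR (Simes) on transcripts that made up at least 5% of their gene, and repeated with voom and diffSplice of limma. Shares are percent of a gene's estimated counts. Numeric work outside R and the figures used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

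The groups, comparisons, tests, lists, alternatives other than those named below, and the rule for named genes were set before the data were examined. The rule named the edited gene, members of each list with the smallest adjusted p, paralogs, and for each comparison up to 8 rises and 8 falls that were largest among called genes. These genes had a symbol other than a clone name, a mean of at least 1 CPM in 1 group, and all libraries of a group on one side of the other. For usage it named the 5 genes with the smallest p and the members of the MBNL list. For the wild-type sets the 10 genes with the smallest p were named, a choice made later. Genes named outside this rule made up a short list of calls, are further list members given as examples, or are said to have been chosen after their values were seen.

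The procedure was tested on simulated data, with 200 genes changed per set. It recovered 43.3 to 59.7% of genes changed 1.5-fold, 55.2 to 80.6% of those changed 2-fold and 86.4 to 97.0% of those changed 4-fold, with 4 to 15 false calls among 135 to 171. Camera called the shifted list in each of 5 simulations and 0 of 20 unshifted lists. Genes were simulated independently and these lists were drawn at random, so false calls of camera on lists whose genes move together were not tested. For usage, diffSpliceDGE recovered 0 of 67 genes shifted 1.5-fold or 2-fold and 3.03 to 12.1% of those shifted 4-fold. Voom recovered 22.7, 30.3 and 40.9% of those shifted 4-fold, with 9 of 33, 7 of 33 and 3 of 37 calls false. Libraries of a group were checked for duplicated data, and the smallest chi-square per degree of freedom between any pair was 2.80.

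Alternatives were DESeq2 1.42.0, RLE scaling, no filter, the Salmon gene counts, only the libraries of the groups compared, all 36 trophoblast libraries in one model, leaving out each library in turn, a replicate block for wild-type contrasts, other minimum shares and gene-level tests for usage, and other set tests. Added after the data were seen were the share of reads in no gene as a covariate, voom for usage, and the 9 wild-type trophoblast libraries together as controls. No library was left out of the analysis.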

Results

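RNA sequencing was measured in 48 libraries made from KOLF2.2J, an established human induced pluripotent stem cell line, and from clones of it in which a premature stop codon had been edited into 1 of 11 genes. Of these, 36 libraries came from cells differentiated for 6 days towards the trophoblast, the outer lineage of the embryo that forms the placenta, under conditions that favour a primitive syncytium, the first multinucleated layer of the placenta. The other 12 came from cortical brain organoids, 3-dimensional cultures patterned towards the dorsal forebrain, sampled at day 8 or day 22. The trophoblast libraries formed 3 sets of 4 groups, each with its own wild-type cultures. Set A held the HEY1, HOPX and MAFF knockouts, set B the MBNL2, MBNL3 and TWIST2 knockouts, and set C the DLX4, DLX5 and DLX6 knockouts. The SIX3 knockout was compared with wild-type organoids at day 8 and the NR2F1 knockout with wild-type organoids at day 22. Each of the 16 groups had 3 libraries, from 3 knockout clones or 3 parental cultures. Gene counts per library summed to 18 to 27.9 M in trophoblast and 29.4 to 37.8 M in organoids. Levels below are counts-per-million (CPM) as mean ± SD over n = 3 libraries, and log2 changes are knockout minus wild type. The p-values measure the spread between these clones and cultures, and a knockout clone also differs from wild type in having been edited and cloned.

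The first question was whether the edited gene's transcript differed in its own knockout. Adjusted over all genes, it fell in 8 of the 11 knockouts. DLX5 (ENSG00000105880), a homeobox gene, went from 43.8 ± 2.33 to 11.3 ± 3.30 CPM (log2 change -1.96, adjusted p = 0.013), and HEY1 (ENSG00000164683), a transcriptional repressor of the Notch pathway, from 132 ± 13.9 to 42.2 ± 6.33 CPM (-1.64, adjusted p = 0.0027). DLX6 (ENSG00000006377) fell from 16.7 ± 0.491 to 6.51 ± 0.615 CPM (-1.36), MBNL2 (ENSG00000139793) from 201 ± 14.7 to 83.7 ± 4.94 CPM (-1.26) and MBNL3 (ENSG00000076770) from 2073 ± 66.8 to 1116 ± 181 CPM (-0.89). Smaller falls were seen for MAFF (ENSG00000185022), from 104 ± 3.10 to 64.9 ± 11 CPM (-0.67), SIX3 (ENSG00000138083), from 65.6 ± 9.62 to 46.2 ± 5.89 CPM (-0.50), and NR2F1 (ENSG00000175745), from 304 ± 9.81 to 227 ± 13.7 CPM (-0.43). In each of these 8 all 3 knockout libraries lay below all 3 wild-type ones. HOPX (ENSG00000171476) was at 255 ± 5.68 against 418 ± 10.7 CPM (-0.71), with no overlap. It passed alone (unadjusted p = 2.9e-05) but not over all genes (adjusted p = 0.54). DLX4 (ENSG00000108813) was at 48.0 ± 11.3 against 46.1 ± 4.44 CPM (adjusted p = 0.98), and TWIST2 (ENSG00000233608) at 53 ± 13.3 against 34.3 ± 5.91 CPM (log2 change 0.62, unadjusted p = 0.0020, adjusted p = 0.24). RNA level does not report on the protein, and a gene-level count does not show whether the stop codon is present.

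**Figure D1:**
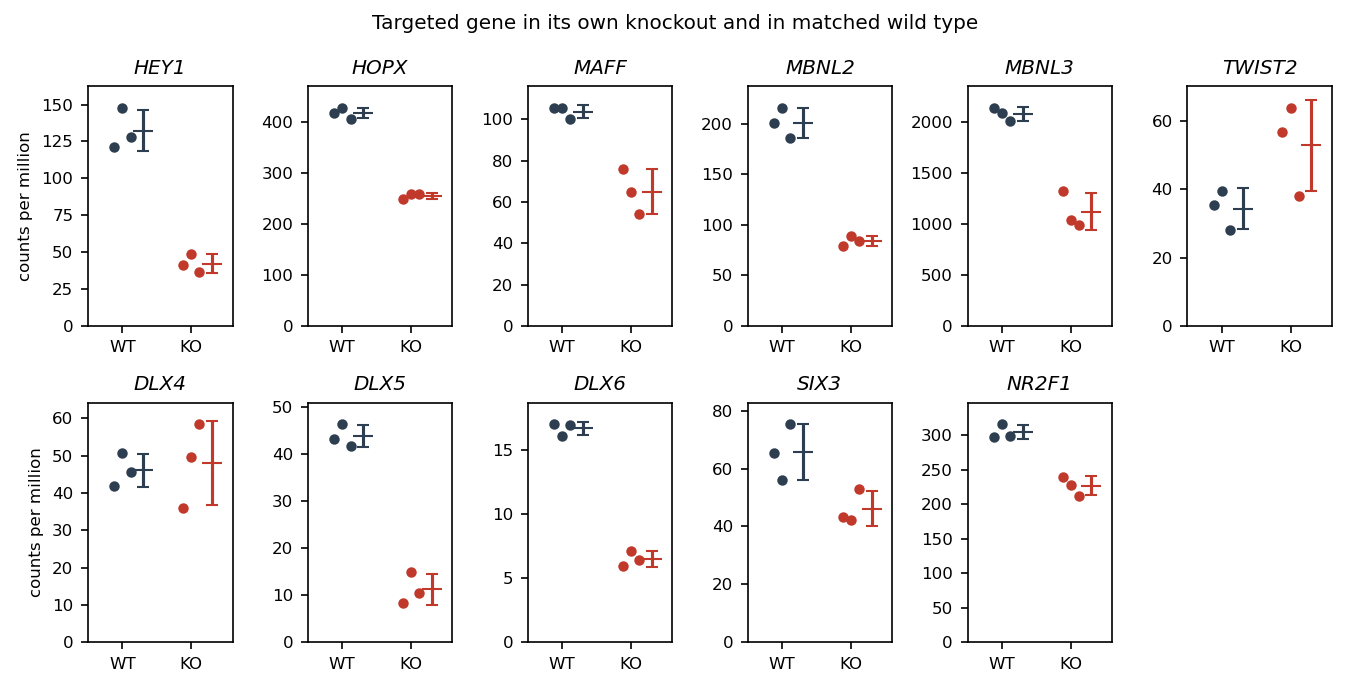
Level of the edited gene in each library of its own knockout (3 clones) and of the matching wild type (3 cultures), in CPM on a linear axis from 0. Points are libraries, and bars give the mean and SD. Knockout and wild-type points do not overlap in any panel except DLX4 and TWIST2; DLX5 fell from a mean of 43.8 to 11.3.

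According to the labels, each edit covered 3 bases, given here in GRCh38 coordinates. All 11 lay in coding sequence, and no annotated exon of another gene contained any of them. Introns of other genes were not checked. The HEY1 edit lay on chromosome 8 at 79767069 to 79767071 in exon 3 of 5, the HOPX edit on chromosome 4 at 56655947 to 56655949 in exon 2 of 3, and the MAFF edit on chromosome 22 at 38214567 to 38214569 in exon 3 of 3. In set B the MBNL2 edit lay on chromosome 13 at 97343109 to 97343111 in exon 4 of 7, the MBNL3 edit on chromosome X at 132392260 to 132392262 in exon 3 of 9, and the TWIST2 edit on chromosome 2 at 238848396 to 238848398 in exon 1 of 2. In set C the DLX4 edit lay on chromosome 17 at 49973225 to 49973227 in exon 2 of 3, the DLX5 edit on chromosome 7 at 97024372 to 97024374 in exon 1 of 3, and the DLX6 edit on the same chromosome at 97006278 to 97006280 in exon 1 of 3. The SIX3 edit lay on chromosome 2 at 44942366 to 44942368 in exon 1 of 2, and the NR2F1 edit on chromosome 5 at 93588192 to 93588194 in exon 2 of 3.

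Libraries within a group differed in the share of aligned reads that fell in no annotated gene, which ranged from 16.2 to 35.5% in trophoblast and from 16.6 to 36.6% in organoid libraries. It separated knockout from wild type without overlap in 4 comparisons. It was lower in the HEY1 knockout (18.6 to 18.8% against 19.9 to 21.8%), the DLX4 knockout (21.1 to 22.4% against 23.8 to 24.6%) and the NR2F1 knockout (16.6 to 19.0% against 23.5 to 29.7%), and higher in the DLX6 knockout (25.9 to 35.5% against 23.8 to 24.6%). In the TWIST2 knockout it was 16.2, 16.5 and 23.1%, against 18.8 to 23.7% in the wild type of set B. The share is given beside the gene groups below because it moved with several of them. Over the 11 knockout comparisons, camera with a preset correlation called 79 of 249 list tests, 45 higher and 34 lower. None of them passed with an estimated correlation, and fry called 17, of which 15 were also called by camera.

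**Figure D2:**
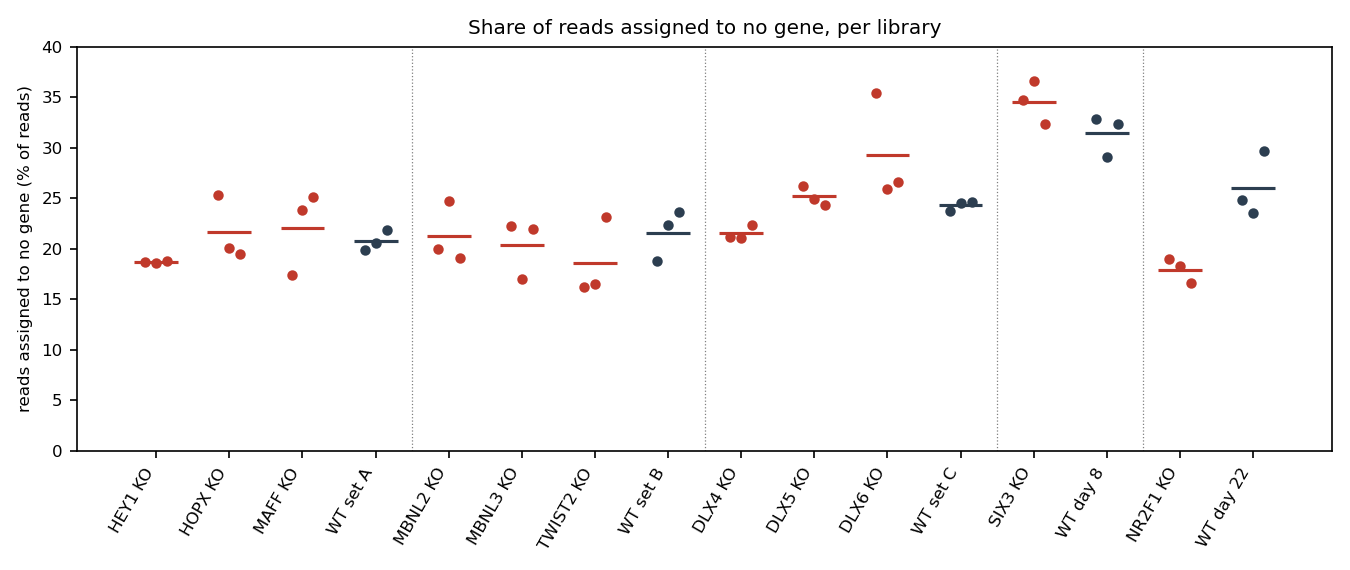
Percent of reads that fell in no annotated gene, on the vertical axis, for each of the 48 libraries, arranged by group, with knockout and wild-type libraries in different colours. The NR2F1 knockout (16.6 to 19.0%) sits below its wild type (23.5 to 29.7%), and TWIST2 knockout replicate 3 (23.1%) sits apart from replicates 1 and 2 (16.2 and 16.5%).

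In set A the HEY1 knockout was compared with wild type to ask which genes differ in trophoblast cells in which this Notch-pathway repressor was edited. HES1, another repressor of the same family and a direct Notch target, rose from 13.7 ± 1.39 to 25.6 ± 2.71 CPM (log2 change 0.91, adjusted p = 0.0034). TRIM58, an E3 ubiquitin ligase of the red cell lineage, rose from 1.74 ± 0.614 to 21.4 ± 5.53 CPM (3.63), and so did OR2W3, an olfactory receptor gene that shares its locus, from 0.0592 ± 0.0287 to 0.887 ± 0.197 CPM (3.81). The 2 overlap, and the strand setting of the counting was not given, so reads of one may be counted for the other. AHNAK2, a large scaffold protein, rose by 0.91 and DPP4, a cell-surface peptidase, by 0.54 (66.7 ± 4.66 against 45.9 ± 1.81 CPM). With HEY1 itself, these were the 6 genes called of 18408 tested, 5 higher and 1 lower. Of 14 tested Notch pathway genes, HES1 rose and HEY1 fell, and adjusted over the list alone 3 were higher and 1 lower (HES5 at 1.05, adjusted p = 0.34 over all genes). The list's median (0.06) and mean (-0.08) differ in sign. No member of the other 22 lists passed, and adjusted over the list alone 12 members of 5 of them did. Camera called 4 lists. They were p53 targets (13 of 15 higher, adjusted p = 0.00052, and adjusted p = 0.66 with an estimated correlation), endoderm (adjusted p = 0.00082 and 0.46), hypoxia and glycolysis (16 of 17 lower, adjusted p = 0.0070 and 0.72) and extravillous trophoblast (11 of 14 lower, adjusted p = 0.044 and 0.66). Of 5 endoderm genes 3 were higher adjusted over the list alone (SOX17, a transcription factor of definitive endoderm, at 1.08), and fry called this list too. Of the paralogs, HEYL was at -0.76 and HES2 at -0.11, and neither passed. The knockouts' share of reads in no gene was below that of wild type (above), and with that share in the model 522 genes were called. DESeq2 called 41 genes. Without wild-type replicate 3 of set A the count was 1.

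HOPX encodes a small homeodomain protein that does not bind DNA. In its knockout no gene was called by edgeR among 18408 tested, including HOPX itself, with 856 at an unadjusted p under 0.05 (4.65% of genes). DESeq2 called 1 gene, HOPX, which was also the 1 gene called with the share of reads in no gene in the model. Leaving out HOPX knockout replicate 2 gave 1 called gene. No member of the 23 lists passed, and adjusted over the list alone 1 did, VTCN1, a B7-family surface protein of the amnion list, at 0.24. Camera called 5 lists, of which the amnion list was higher (adjusted p = 0.0011) and syncytiotrophoblast, cytotrophoblast, stress response and mitochondrial genes lower. The smallest was adjusted p = 0.66 with an estimated correlation. The highest share of reads in no gene in set A was that of HOPX knockout replicate 1, at 25.4%.

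MAFF is a small MAF protein that pairs with NRF2 and related factors. In its knockout CGB5, which encodes a beta subunit of the pregnancy hormone chorionic gonadotropin, fell from 168 ± 19.9 to 85.1 ± 12.8 CPM (log2 change -0.98, adjusted p = 0.036), though reads are shared among the near-identical CGB genes. TCL6, a non-coding RNA, fell from 77.5 ± 4.54 to 39.3 ± 7.10 CPM (-0.98), and PLA2G2F, a secreted phospholipase, fell by 1.04 on the log2 scale. The prolactin receptor PRLR fell from 189 ± 12.6 to 135 ± 14.7 CPM (-0.48) and the kinase SIK1 from 18.6 ± 1.73 to 13.0 ± 0.666 CPM (-0.52). The potassium channel subunit KCNE3 was the single gene that rose, from 3.97 ± 0.206 to 6.55 ± 0.139 CPM. In all, 14 of 18408 genes were called, 13 of them lower; the others, besides MAFF, were AGXT2 (-1.24), PROB1 (-0.73), POF1B (-0.73), EXPH5 (-0.47), C2CD2 (-0.48), RELL1 (-0.43) and PPM1H (-0.34). Of 26 syncytiotrophoblast genes, CGB5 fell, and adjusted over the list alone 4 were lower, among them CGB3 at -0.88 and CGB8 at -0.76. Camera called this list lower (adjusted p = 2.2e-06, and 0.66 with an estimated correlation). The amnion list (7 higher and 1 lower of 11, adjusted over the list alone) and the interferon list (4 of 11) were called higher (adjusted p = 0.66 with an estimated correlation for both). Camera called 7 more lists, none of which passed with an estimated correlation. Extravillous trophoblast, Notch, hypoxia, stress response and immediate early genes were lower and mesenchyme and mitochondrially encoded genes higher. No member of the other 22 lists passed over all genes. None of the 16 NRF2 targets passed by either adjustment. The paralogs MAFK (-0.50, adjusted p = 0.19) and MAFG (0.20, adjusted p = 0.24) did not pass. Without MAFF knockout replicate 1, the library with the lowest share of reads in no gene in set A (17.4% against 23.8 and 25.2% in its group), the count was 326. Without MAFF knockout replicate 3 or any 1 of the 3 wild-type libraries it was 0, and DESeq2 called 239. Of 19 genes followed in this knockout, 9 no longer passed and 1 newly passed with the 9 wild-type trophoblast libraries as controls.

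MBNL2 and MBNL3 encode RNA-binding proteins that regulate alternative splicing and RNA localisation, and both were knocked out in set B. In the MBNL2 knockout, MBNL2 was the single gene called of 18154 (2071 at an unadjusted p under 0.05, and 52 called by DESeq2). MBNL1 was at -0.15 and MBNL3 at 0.10, neither of which passed. No other member of the 23 lists passed over all genes. Adjusted over the list alone, 14 of 17 hypoxia and glycolysis genes were higher, among them EGLN3, an oxygen-sensing hydroxylase, at 1.13, and NDRG1 at 1.14. Camera called the list (adjusted p = 2.9e-08, and 0.66 with an estimated correlation). The wild type of set B was itself low in this list, with a median log2 difference of -0.27 from that of set A, and 14 of the 17 genes were higher in the knockout than in the wild type of sets A and C too. Adjusted over the list alone 5 of 10 interferon genes were lower (IFIT1 at -0.74), which camera (adjusted p = 0.015, and adjusted p = 0.46 with an estimated correlation) and fry (adjusted p = 0.021) both called. Camera called 9 more lists, none of which passed with an estimated correlation (adjusted p = 0.46 for p53 and 0.66 for the others). Syncytiotrophoblast, extravillous trophoblast, Notch, stress response and immediate early genes were higher and amnion, mesenchyme, p53 and mitochondrially encoded genes lower. Fry called the p53 list too (adjusted p = 0.045). Of the 23 syncytiotrophoblast genes above the wild type of set B, 1 was above that of both other sets. Leaving out wild-type replicate 2 of set B gave 2 called genes.

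The MBNL3 knockout differed more widely, with 633 genes higher and 513 lower of 18154 (219 changed more than 2-fold). Genes of the syncytiotrophoblast, the hormone-producing layer of the placenta, were among those that rose. CGA, the alpha subunit of chorionic gonadotropin, rose by 1.10 on the log2 scale, from 4402 ± 1024 to 9449 ± 1297 CPM, and LEP, the hormone leptin, from 2.72 ± 2.11 to 17.9 ± 9.69 CPM (2.71). The beta-subunit genes CGB3, CGB5 and CGB8 rose by 1.75, 1.96 and 1.57, with reads shared between them. In all 5 of 26 genes of this list rose and none fell (9 and 0 adjusted over the list alone). Camera called the list higher (adjusted p = 0.00012, and 0.66 with an estimated correlation). The wild type of set B was itself low in this list, with a median log2 difference of -0.41 from that of set A. Of the 22 members above it in the knockout, 9 were above the wild type of both other sets and 7 below both.

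Of 14 genes of extravillous trophoblast, the invasive cells of the placenta, 6 rose and 1 fell (9 and 1 adjusted over the list alone), and camera called the list (adjusted p = 0.00083, and adjusted p = 0.66 with an estimated correlation). They included the deiodinase DIO2 (1.10), the matrix protease MMP2 (0.78), the transcription factor ASCL2 (2.13) and FLT1, a receptor for vascular growth factor (2.87, from 3.86 ± 2.84 to 28.2 ± 12.8 CPM); HLA-G rose by 0.49, and FN1, fibronectin, fell by 0.58. Of 17 hypoxia and glycolysis genes 6 rose and none fell (12 and 0 adjusted over the list alone), including PDK1 (0.78), EGLN3 (1.59), the glucose transporter SLC2A3 (0.92) and PFKFB4 (0.64). Camera called the list (adjusted p = 4.4e-06, and 0.66 with an estimated correlation). Of 16 NRF2 targets none rose and 5 fell (0 and 7 adjusted over the list alone), among them the cystine transporter SLC7A11 (-0.89) and NQO1 (-0.84), and camera called the list lower (adjusted p = 0.0053, and adjusted p = 0.66 with an estimated correlation). Of 15 p53 targets 2 fell, FAS (-1.42) and ZMAT3 (-0.66), with 6 lower adjusted over the list alone (camera adjusted p = 0.0089, and adjusted p = 0.66 with an estimated correlation). Of 13 cholesterol synthesis genes HMGCR, the rate-limiting enzyme, fell by 0.26 on the log2 scale, with 5 lower adjusted over the list alone; camera (adjusted p = 0.0052, and adjusted p = 0.46 with an estimated correlation) and fry both called the list.

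The other lists were not called by camera in this knockout, while fry called the MBNL and interferon lists (adjusted p = 0.022 each). In cytotrophoblast, the progenitor layer, TP63 (1.11) and ITGB4 (0.68) rose and KRT7 (-0.60) and PEG10 (-0.42) fell of 19 (2 and 5 adjusted over the list alone). Of 11 amnion genes HAND1 (-0.99), BAMBI (-0.70) and ITGB6 (-0.81) fell (2 higher and 4 lower adjusted over the list alone). Each of these named genes was highest in set B among the wild types of the trophoblast sets. In the cell cycle list 4 rose and 1 fell of 21 by either adjustment, with RRM2 at 0.66 and MCM5 at -0.50. The steroid synthesis enzymes FDX1 (0.88) and CYP11A1 (0.80) rose of 8 tested by either adjustment. Of 24 MBNL family genes and reported targets INSR rose (0.70) and 4 fell, among them MBNL3 and SPTAN1 (-0.53), with 2 and 5 adjusted over the list alone. One member each rose in the endothelium (EGFL7, 0.82), Notch (NOTCH3, 0.72) and immediate early lists (NR4A1, 1.55), where 3, 4 and 5 were higher and 0, 0 and 2 lower adjusted over the list alone. One member each fell in the pluripotency (ESRG, -1.27), mesenchyme (LUM, -0.56), DLX (DLX2, -1.84), interferon (MX1, -0.45) and mitochondrial lists (MT-ND2, -0.50). In these, 0, 2, 1, 0 and 0 were higher and 1, 5, 1, 4 and 1 lower adjusted over the list alone. No member of the other 4 lists passed.

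**Figure D3:**
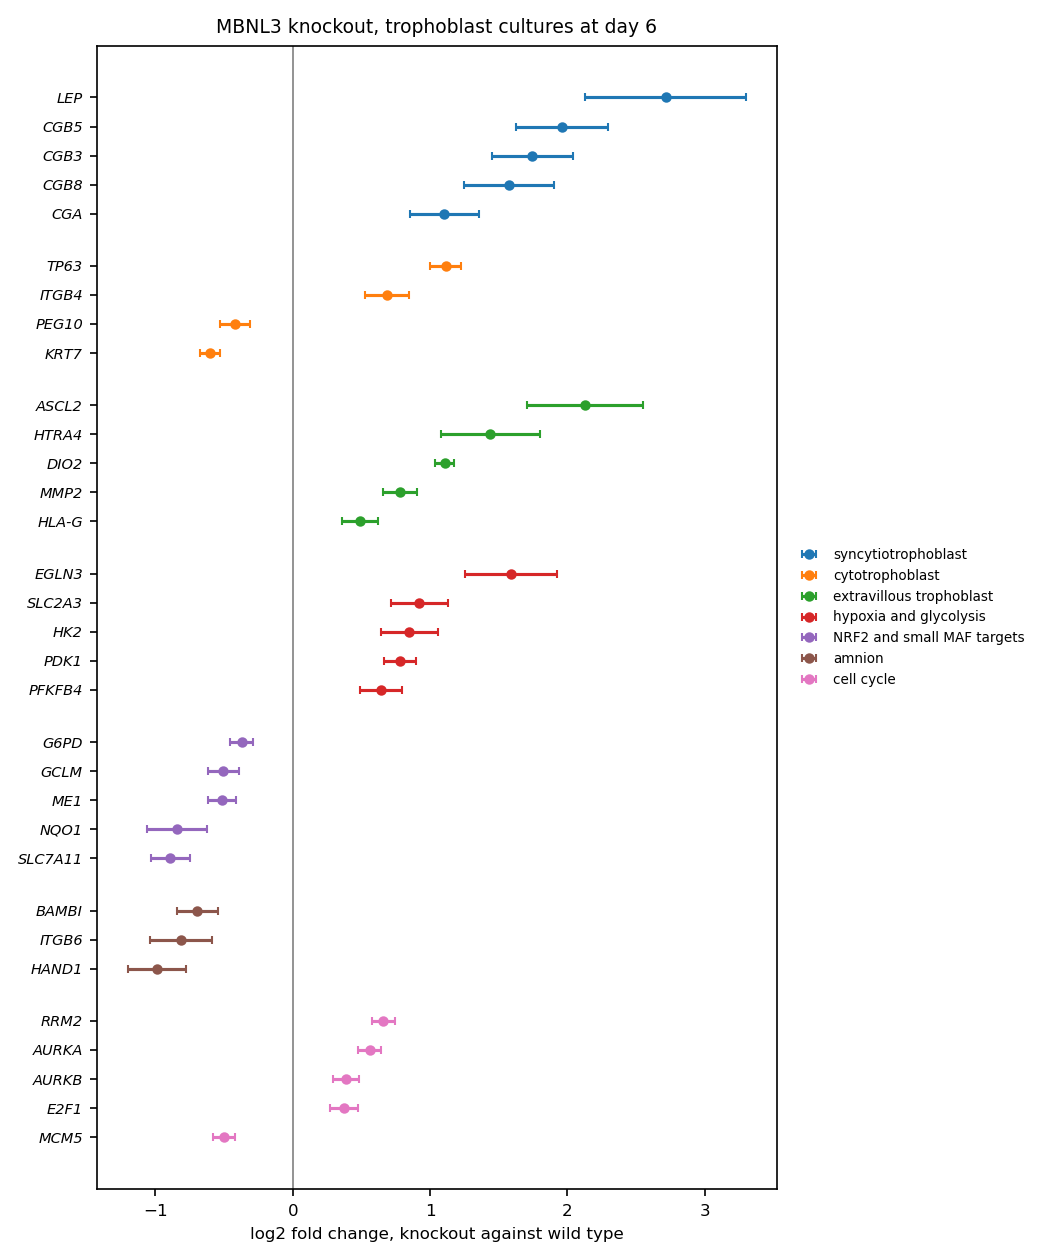
Log2 change of called members of selected fixed gene lists in the MBNL3 knockout against the wild type of set B (n = 3 libraries each). Each point is a gene, placed on the horizontal axis by log2 change, with a standard error bar and a colour for its list. Only the members with the smallest adjusted p of each list, all under 0.05 over all genes, are drawn. In the syncytiotrophoblast list 5 genes rose and none fell, and in the NRF2 list none rose and 5 fell.

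Other large rises were of TNFSF10, a death-receptor ligand (3.20), the gonadotropin gene CGB1 (3.11), the water channel AQP1 (2.82), GPRC5C (2.68), KISS1R, the receptor of kisspeptin (2.45), and the epoxygenase CYP2J2 (2.29). Other large falls were of the hyaluronan receptor CD44 (-1.87, a member of the MBNL list), the oxidase NOX4 (-1.86), FSHR (-1.84), OLFML2A (-1.84), AADACL3 (-1.78), LRRC3B (-1.76) and the chemokine CX3CL1 (-1.64, from 5.77 ± 0.632 to 1.81 ± 0.434 CPM). Of 59 genes followed in this knockout, 17 no longer passed and 0 changed direction with the 9 wild-type trophoblast libraries as controls. The knockout and the wild type of set B did not overlap for 28.8% of genes, where chance gives 10%. In the other trophoblast knockouts this ran from 11.2% (TWIST2) to 24.3% (DLX6, with 1 called gene). The paralog MBNL2 was at 0.28 (adjusted p = 0.21) and MBNL1 at 0.19. The share of reads in no gene was 22.2, 17.0 and 22.0% in the knockout and 18.8, 22.3 and 23.7% in wild type. The count fell to 407 and 322 without knockout replicates 2 and 3, and to 272 and 309 without wild-type replicates 1 and 3. Fewer genes were higher than lower with RLE scaling (535 and 546), without knockout replicate 2 or 3 (190 and 217, 156 and 166) and without wild-type replicate 3 (135 and 174).

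MBNL2 and MBNL3 knockouts were also compared directly, and 220 genes differed, 141 of them higher in the MBNL2 knockout. The tight-junction gene CLDN1 was at 44.5 ± 5.39 against 19.8 ± 0.661 CPM (log2 difference 1.17), CX3CL1 at 5.46 ± 0.801 against 1.81 ± 0.434 CPM (1.57), and NCF2, a subunit of the phagocyte oxidase, at 1.55. TREX2 (1.76), HKDC1 (1.48), NPIPB6 (1.32, one of a family of near-identical genes), RTL5 (1.22) and S1PR1 (1.19) were also higher. DIO2 was lower in the MBNL2 knockout (65.9 ± 1.65 against 110 ± 1.89 CPM, -0.74), as were S100A9 (-1.80), MBNL2 itself (-1.55), KISS1R (-1.39), IGSF8 (-0.92), PLCG2 (-0.83), IKZF2 (-0.77) and KCTD17 (-0.75). Without 1 of the 6 libraries the count was 86, 62 and 68 (MBNL2 knockout replicates 1 to 3) or 142, 81 and 69 (MBNL3 knockout replicates 1 to 3). No gene was called in the same direction in both knockouts by edgeR, where 0.028 would be expected from the counts called and simulated unchanged groups with shared controls gave 0, and DESeq2 gave 43. Without wild-type replicate 2 of set B there was 1. At an unadjusted p under 0.05 the number was 1240, against 231 expected and 181 simulated. The covariance of the 2 sets of log2 changes was 0.088, against 0.033 simulated. Taken from differences of mean log2 CPM it was 0.077, and 0.051 (0.034 to 0.062 over 6 divisions) when the wild-type libraries were divided between the knockouts so that none was shared.

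TWIST2 encodes a basic helix-loop-helix factor of mesenchymal cells. In its knockout no gene was called of 18154 by edgeR, with 3146 at an unadjusted p under 0.05 (17.3% of genes) and 2 called by DESeq2. The paralog TWIST1 was at 0.14 (adjusted p = 0.66). No member of the 23 lists passed, while 92 members of 14 lists did adjusted over the list alone. Among these, 16 of 26 syncytiotrophoblast genes (CGA at 0.80), 15 of 17 hypoxia and glycolysis genes (SLC2A1, a glucose transporter, at 0.79) and 12 of 15 stress response genes (ATF3 at 1.01) were higher, and none of these 3 lists had a lower one. The wild type of set B was itself low in them (median log2 difference from set A of -0.41, -0.27 and -0.28), and 17, 17 and 13 members were above the wild type of both other sets. Camera called these 3 lists at adjusted p = 5.5e-08, 5.5e-08 and 2.2e-06, each with adjusted p = 0.66 with an estimated correlation. It called 6 more, none of which passed with an estimated correlation. Cytotrophoblast, extravillous trophoblast, Notch, steroid synthesis and immediate early genes were higher and pluripotency genes lower. The share of reads in no gene moved with them (16.2, 16.5 and 23.1% in replicates 1 to 3). Without TWIST2 knockout replicate 3, 4192 genes were called, 2683 higher and 1509 lower. Since HOPX, TWIST2 and DLX4 had no called gene, none could be called in all 3 knockouts of a set by edgeR. At an unadjusted p under 0.05 170, 494 and 77 genes were higher in all 3 knockouts of the set and 71, 341 and 77 lower, where simulated unchanged groups with shared controls gave means of 41.1, 44.6 and 42.6 higher and 29.5, 27.1 and 29.6 lower.

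Transcript usage, the share of a gene's transcripts taken by each isoform, was compared in set B because MBNL proteins regulate splicing. In the MBNL3 knockout COL5A1-202, a transcript of a fibrillar collagen gene, made up 1.37 ± 0.800% of its gene against 18.1 ± 0.744% in wild type, and INF2-203, of a formin that regulates actin, was not detected against 20.3 ± 1.95%. These differences were called by both diffSpliceDGE (adjusted p = 2.3e-06 and 3.8e-18) and voom with diffSplice (2.8e-06 and 0.00012). Of 23 MBNL family genes and reported targets, 3 changed in the MBNL3 knockout by each method, the edited MBNL3 among them, and 5 and 4 adjusted over the list alone. NUMA1-205, of a spindle protein, fell from 33.3 ± 4.92 to 16.8 ± 3.65%, and MBNL3-212 rose from 2.86 ± 0.352 to 7.01 ± 1.10%, by both methods. KIF13A-213 went from 7.39 ± 1.16% to not detected by diffSpliceDGE alone, and MBNL2-201, at 31.9 ± 7.44 against 50.5 ± 4.20%, passed by voom alone (adjusted p = 0.012). In the MBNL2 and TWIST2 knockouts no list member passed by either method, and MBNL2 was the one with 1 adjusted over the list alone. PDLIM2-207, FGFR3-205 and ZNF83-205 were the other smallest p-values in the MBNL3 knockout; FGFR3-205 (39.3 ± 9.76%) and ZNF83-205 (28.4 ± 3.53%) were not detected in wild type. Voom called none of these 3 (adjusted p = 0.31, 0.33 and 0.27). The same transcripts were in the TWIST2 knockout at 5.55 ± 3.38% (PDLIM2-207) and 17.0 ± 12.8% (ZNF83-205).

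The counts of genes with changed usage were 30, 61 and 30 of 9295 for the MBNL2, MBNL3 and TWIST2 knockouts by diffSpliceDGE and 3, 69 and 1 by voom, with 1, 20 and 1 called by both. In the MBNL2 knockout GPATCH2L-214, RNPS1-219, FGFR3-205, ZNF83-205 and SPRY4-201 had the 5 smallest p-values by diffSpliceDGE. Voom called none of these 5 (adjusted p = 0.68, 0.79, 0.62, 0.72 and 0.56). The 3 genes that voom called were MBD2 (MBD2-202 at 24.5 ± 4.42 against 9.20 ± 0.621%), INF2 (INF2-202 at 18.3 ± 0.601 against 6.40 ± 1.99%) and CD47 (CD47-202 at 19.0 ± 0.538 against 10.3 ± 0.746%). Of these INF2 was also called by diffSpliceDGE (adjusted p = 0.017). In the TWIST2 knockout the 5 smallest p-values by diffSpliceDGE were of PDLIM2-207, ZNF83-205, ESPL1-207, YWHAZ-216 and SPRY4-201. YWHAZ-216 was at 8.43 ± 3.51 against 2.26 ± 0.883%, and it was the single gene there that voom also called. In counts with simulated shifts diffSpliceDGE recovered 0 of 67 shifted genes at 2-fold and 3.03 to 12.1% at 4-fold, and 19 of 27, 2 of 4 and 14 of 19 of its calls were false. The diffSpliceDGE calls of 2 knockouts shared 14 to 18 genes, where under 0.2 would be expected from the counts called and simulated unchanged transcripts with shared controls gave means of 3.25 to 3.65 (at most 9), and those of voom shared at most 1. All 3 knockouts were compared with the same 3 wild-type libraries, in which FGFR3-205, ZNF83-205, SPRY4-201 and PDLIM2-207 were at 0%. Without wild-type replicate 3 of set B the counts were 14, 24 and 14, without wild-type replicate 1 that of MBNL3 was 32, and without MBNL3 knockout replicate 3 it was 37. Without TWIST2 knockout replicate 1 or 3 the TWIST2 count was 19 or 52.

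DLX4, DLX5 and DLX6 encode homeobox factors of 1 family, and set C asked what differs when each is edited. In the DLX5 knockout DLX5 was the single gene called of 18346, and in the DLX6 knockout DLX6 was. No gene was called in the DLX4 knockout by edgeR (961 at an unadjusted p under 0.05, and 2 by DESeq2). The neighbours and paralogs did not pass in any of the 3: DLX6 was at 0.22 and its antisense transcript DLX6-AS1 at 0.18 in the DLX5 knockout, DLX5 was at -0.29 in the DLX6 knockout, and DLX3, the most abundant member (346 ± 12.8 CPM in wild type), was between -0.23 and 0.02. DLX2 was at 0.880 ± 0.167, 0.968 ± 0.386 and 1.17 ± 0.892 CPM in the 3 knockouts against 0.344 ± 0.0746 CPM, and did not pass. Apart from the edited gene in the DLX list, no member of the 23 lists passed in the 3 knockouts, and 2, 6 and 30 members, the edited gene of the DLX5 and DLX6 knockouts included, did adjusted over the list alone. In the DLX6 knockout these included 4 of 16 NRF2 targets, all lower (SLC7A11 at -0.41, MAFK at -0.56), a list that camera (adjusted p = 0.0028, and adjusted p = 0.46 with an estimated correlation) and fry (adjusted p = 0.0083) both called. The syncytiotrophoblast (adjusted p = 2.7e-06) and stress response lists (adjusted p = 2.5e-05) were called lower by camera there (adjusted p = 0.66 with an estimated correlation for both), with 1 of 26 and 3 of 15 lower adjusted over the list alone. Camera also called extravillous trophoblast, hypoxia and immediate early genes lower and amnion genes higher there, none passing with an estimated correlation. In the DLX4 knockout camera called the cholesterol synthesis list higher (adjusted p = 0.0099, and adjusted p = 0.46 with an estimated correlation), as did fry, with LDLR at 0.26, and also syncytiotrophoblast, hypoxia and steroid synthesis genes higher. In the DLX5 knockout it called the interferon list higher (adjusted p = 7.8e-05, and adjusted p = 0.46 with an estimated correlation), with ISG15 at 0.53, amnion and mesenchyme genes higher, and NRF2 targets lower. No list called in the DLX4 or DLX5 knockout passed with an estimated correlation. DESeq2 called 16 genes in the DLX5 knockout and 80 in the DLX6 knockout. The share of reads in no gene was below wild type in the DLX4 knockout and above it in the DLX6 knockout. Without DLX5 knockout replicate 1 or 3 or any 1 of the 3 wild-type libraries the DLX5 count was 0.

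In direct contrasts, DLX5 alone differed between the DLX4 and DLX5 knockouts (log2 difference 2.10, 48.5 ± 8.77 against 11.3 ± 3.30 CPM), and DLX6 alone between the DLX4 and DLX6 knockouts (1.55). Between the DLX5 and DLX6 knockouts DLX6 (1.58), DLX5 (-1.67) and MX2 differed; MX2, an interferon-induced antiviral protein, was at 26.4 ± 1.52 against 11.4 ± 2.20 CPM (1.21, adjusted p = 0.016). Without DLX4 knockout replicate 1 the DLX4 and DLX6 knockouts differed in 1085 genes, and DESeq2 called 17. Without DLX5 knockout replicate 3 the DLX4 and DLX5 knockouts differed in 0, and the DLX5 and DLX6 count was 1 without DLX5 knockout replicate 1 or 3 or DLX6 knockout replicate 2. No gene was called in the same direction by edgeR in any pair of the 3 knockouts, with 0 expected and 0 simulated. At an unadjusted p under 0.05 the DLX4 and DLX5 knockouts shared 289 genes (24.9 expected, 183 simulated), DLX4 and DLX6 252 (77.2 and 186), and DLX5 and DLX6 507 (76.9 and 189). The covariances of their log2 changes were 0.040, 0.025 and 0.051, against 0.034 simulated for each pair. Taken from differences of mean log2 CPM they were 0.032, 0.019 and 0.042, and with the wild-type libraries divided so that no control was shared 0.0093 (0.0067 to 0.014), -0.0035 (-0.015 to 0.0076) and 0.019 (0.0070 to 0.030). DESeq2 gave 1 shared call for DLX4 and DLX5 and 9 for DLX5 and DLX6.

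SIX3 is a homeobox factor of the anterior neural plate and eye field, and its knockout was compared with wild type in organoids at day 8. Genes of the eye field, the part of the forebrain that forms the retina, were lower. RAX fell from 87.2 ± 3.02 to 29.2 ± 3.15 CPM (log2 change -1.58), LHX2 from 9.50 ± 0.804 to 1.26 ± 0.0753 CPM (-2.91) and SIX6 from 6.83 ± 1.69 to 0.877 ± 0.272 CPM (-2.95), while PAX6 rose by 0.22. Genes that mark more posterior brain regions were higher, such as WNT1, a signal of the midbrain border, from 0.396 ± 0.0816 to 4.55 ± 0.548 CPM (3.51), and the homeobox genes IRX1 (1.98), BARHL1 (2.61) and LMX1B (2.18). Of 20564 genes 819 rose and 1018 fell, and 218 changed more than 2-fold.

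Of 6 tested eye field genes 1 rose and 4 fell by either adjustment, and camera called the list lower (adjusted p = 0.0027, and adjusted p = 0.57 with an estimated correlation). Of 15 genes of diencephalon, midbrain and hindbrain 9 rose and 2 fell (9 and 3 adjusted over the list alone; PAX2 rose by 1.22), and camera called the list higher (adjusted p = 0.0011, and adjusted p = 0.46 with an estimated correlation). Of 17 WNT ligands and targets 9 rose and 2 fell (10 and 3 adjusted over the list alone), with WNT8B (1.70), RSPO2 (1.48), WNT7B (1.33) and the WNT inhibitor DKK1 (3.19) higher and WNT5A (-0.51) lower. Camera called it at adjusted p = 0.0047, with adjusted p = 0.50 with an estimated correlation. In the Notch list 8 of 16 rose and 1 fell by either adjustment (HES5 1.59, HEY1 1.60, JAG1 0.75, HES1 -0.55), called at adjusted p = 0.0010, and adjusted p = 0.46 with an estimated correlation. Of 11 FGF ligands and targets none rose and 6 fell (2 and 6 adjusted over the list alone), including the feedback genes DUSP6 (-0.87) and SPRY2 (-0.46) and the effector ETV5 (-0.97). None of 21 cell cycle genes rose and 10 fell (0 and 11 adjusted over the list alone), by less than the others, with the kinase PLK1 at -0.45 and CCNB1 at -0.44. Camera called these 2 lists lower at adjusted p = 0.0028 and 2.5e-05, with adjusted p = 0.66 with an estimated correlation for both.

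Camera called 5 further lists, each with adjusted p = 0.66 with an estimated correlation. Of 15 genes of the cortical hem and choroid plexus 4 rose and 1 fell (6 and 1 adjusted over the list alone; MSX2 1.25, BMP7 -0.63). Of 13 immediate early genes 4 rose (5 adjusted over the list alone; FOS 0.90, EGR3 0.86), of 13 neuronal genes 2 rose by either adjustment (ELAVL4 2.98, INA 0.25), and of 14 epithelial genes 2 rose (4 adjusted over the list alone; CDH1 0.93). Of 15 p53 targets 3 fell (4 adjusted over the list alone; FAS -0.29).

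Among lists that camera did not call, the telencephalon list had 6 genes up (EMX2 1.54, OTX1 0.69, OTX2 0.47) and 6 down (LHX2, SIX6, HESX1 -0.58) of 16 by either adjustment, and its median (0.04) and mean (-0.16) differ in sign. Neural crest genes rose in 4 of 9 cases (PAX3 1.88, TFAP2A 2.58; 4 and 1 adjusted over the list alone), and placode genes in 3 of 10 by either adjustment (DLX5 2.85, TFAP2C 1.38). Radial glia had 3 up and 2 down of 12 (HES5, FABP7 -0.73; 4 and 3 adjusted over the list alone), pluripotency 3 and 1 of 11 (ESRG 0.64, L1TD1 -0.77; 6 and 3), MBNL targets 1 and 2 of 24 (INSR 0.20, FN1 -0.35; 2 and 3), hypoxia 1 and 2 of 18 (EGLN3 0.72, ADM -1.20; 1 and 4), endothelium 2 and 1 of 6 (KDR 0.65, CDH5 -1.24; 2 and 2), mesenchyme 1 and 0 of 11 (PRRX1 1.78; 1 and 2), and ventral forebrain 2 and 0 of 3 (GAD1 0.65; 2 and 1). By either adjustment endoderm had 1 up and 1 down of 2 (FOXA1 -1.54, CXCR4 0.69), DLX 1 up of 3, NRF2 2 down of 17 (SLC7A11 -0.33), interferon 2 down of 10 (IFITM1 -0.45), the stress response 1 down of 15 (SESN2 -0.38) and cholesterol synthesis 1 down of 13 (FDFT1 -0.26). No member of the other 2 lists passed.

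**Figure D4:**
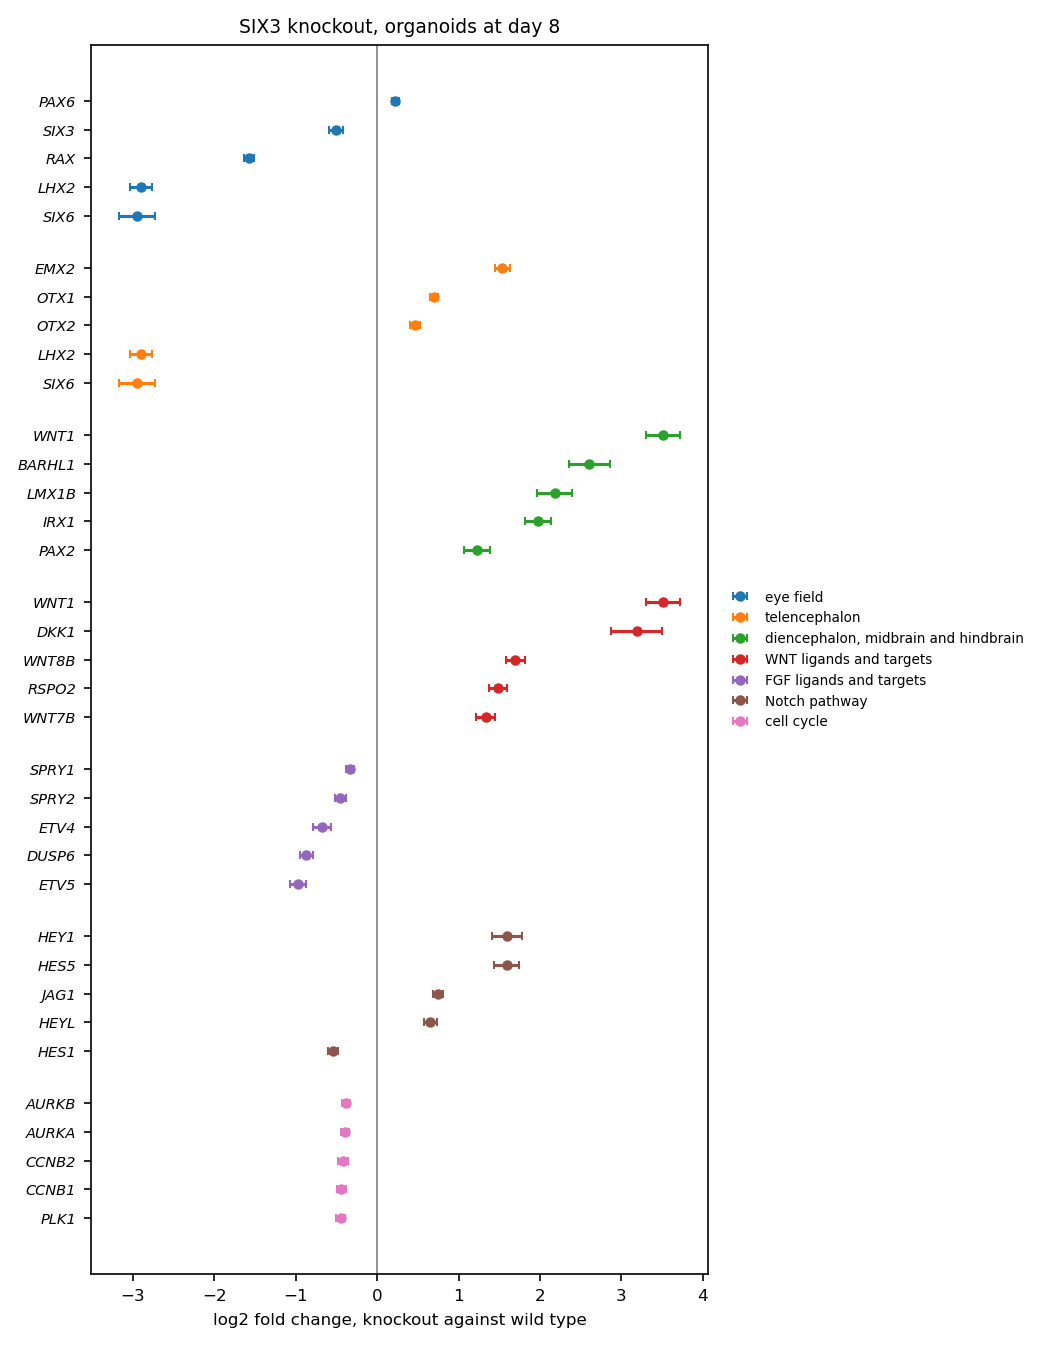
Log2 change of called members of selected fixed gene lists in SIX3 knockout organoids against wild type at day 8 (n = 3 libraries each). Each point is a gene, placed on the horizontal axis by log2 change, with a standard error bar and a colour for its list. Only the members with the smallest adjusted p of each list, all under 0.05 over all genes, are drawn. In the eye field list 4 genes fell and PAX6 rose by 0.22. In the diencephalon, midbrain and hindbrain list, drawn in part, 9 rose and 2 fell.

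The largest other rises were of GALNT14, a glycosyltransferase (3.10, from 7.31 ± 1.46 to 62.9 ± 3.89 CPM), ADAMTS18 (3.19), KLHL4 (2.98) and DMBX1, a homeobox gene of the midbrain (2.87). The largest other falls were of EYA4 (-2.34), SLITRK1 (-1.90), FRRS1L (-1.85) and LHX2-AS1 (-2.73), which is antisense to LHX2 and not told apart from it with certainty. The paralog SIX2 rose from 0.398 ± 0.0616 to 1.23 ± 0.0311 CPM, and SIX1, SIX4 and SIX5 did not pass. The groups did not overlap for 27.0% of genes, where chance gives 10%. The share of reads in no gene was 32.4 to 36.6% in the knockout and 29.1 to 32.8% in wild type, and with it in the model 756 genes were called, 693 of them among the 1837, whose median size of the log2 change went from 0.32 to 0.30, with each in the same direction. Without SIX3 knockout replicate 2, wild-type replicate 1 or wild-type replicate 2 the count was 1221, 1180 or 1070.

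NR2F1 encodes an orphan nuclear receptor that patterns the cortex, and its knockout was compared with wild type in organoids at day 22. All 21 cell cycle genes rose, including the replication helicase genes MCM4 (0.61) and MCM2 (0.67) and the mitotic kinase gene AURKB (0.63). Of 20 neuronal genes 7 fell and none rose, among them the cortical transcription factor BCL11B (-0.70), the microtubule protein MAP2 (-0.37) and reelin, RELN (-0.66). DCT, a melanin synthesis enzyme, rose from 4.84 ± 0.416 to 38.3 ± 9.26 CPM (2.98), and CHAC1, a stress-induced glutathione-degrading enzyme, from 1.51 ± 0.0142 to 9.48 ± 3.02 CPM (2.64). Of 20158 genes 3330 rose and 2802 fell, and 890 changed more than 2-fold, 185 up and 705 down. The share of reads in no gene was 16.6 to 19.0% in the knockout and 23.5 to 29.7% in wild type, and with that share in the model 18 genes were called and 83.0% of the 6132 kept their direction. Of the genes named below DSP, KRT8, KRT19, WNT8B, WNT3A and LMX1A did not keep it.

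Camera called the cell cycle list (adjusted p = 7.0e-11, 21 higher also adjusted over the list alone) and 7 others. Each had adjusted p = 0.66 with an estimated correlation. Of 15 unfolded protein and stress response genes 10 rose (13 adjusted over the list alone), such as the serine synthesis enzymes PSAT1 (0.85) and PHGDH (1.03) and the transcription factor ATF3 (1.30). Of 15 p53 targets 9 rose (10 adjusted over the list alone), including BAX (0.55) and CDKN1A, a cell cycle inhibitor (1.06). Of 13 mitochondrially encoded genes 12 fell (13 adjusted over the list alone), with MT-ND4L at -0.39 and MT-CYB at -0.29. Of 17 NRF2 targets 9 rose and 1 fell (11 and 1 adjusted over the list alone; SLC7A11 1.42, G6PD 0.49), of 16 Notch genes 9 rose and 1 fell by either adjustment (HEY1 0.76, HES1 0.66, JAG1 -0.49), and of 6 pluripotency genes 4 rose by either adjustment (DPPA4 0.52, LIN28A 0.42). The neuronal list, the eighth, had 7 lower adjusted over the list alone. These 8 lists had camera adjusted p-values of 0.029 or less.

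Camera did not call the remaining lists. Of 15 cortical hem and choroid plexus genes 5 rose by either adjustment (MSX2 2.64, WNT8B 2.03, LMX1A 2.02, BMP7 0.72), and of 17 telencephalon genes 4 rose and 4 fell (5 and 4 adjusted over the list alone; EMX1 1.88, OTX2 0.47, and the paralog NR2F2 -0.50). Of 12 FGF genes 2 rose and 3 fell (2 and 4 adjusted over the list alone; FGFR3 -0.90, FGF18 1.30), of 9 neural crest genes 4 fell by either adjustment (TFAP2A -1.67, SOX10 -0.75), and of 12 radial glia genes 3 rose and 2 fell by either adjustment (HES1, PTPRZ1 -0.30). Epithelial genes had 4 up and 1 down of 10 (KRT8 2.19, ESRP2 -0.91; 5 and 1 adjusted over the list alone), placode genes 2 and 3 of 8 (KRT19 1.37, TFAP2A; 3 and 3), cholesterol synthesis 4 and 1 of 13 (LSS 0.35, SC5D -0.23; 5 and 1), MBNL targets 4 and 3 of 25 (BIN1 0.40, CLASP2 -0.27; 4 and 4), and WNT 2 and 1 of 16 (WNT3A 1.63, LEF1 -0.23; 1 and 1). By either adjustment immediate early genes had 4 up of 13 (NR4A1 0.38), mesenchyme 3 of 11 (COL1A1 1.14), hypoxia 3 of 16 (ENO1 0.55), interferon 2 of 11 (IFIT1 0.52), eye field 2 of 8 (VSX2 0.84), endoderm 1 of 1 (CXCR4 0.71) and DLX 1 of 6 (DLX2 0.44). By either adjustment diencephalon, midbrain and hindbrain had 2 up and 1 down of 10 (TCF7L2 0.19, IRX1 -0.91), ventral forebrain 1 and 1 of 10 (GAD2 -0.53) and endothelium 1 and 1 of 3 (EGFL7 1.16, ESAM -1.03). No member of the last list passed.

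**Figure D5:**
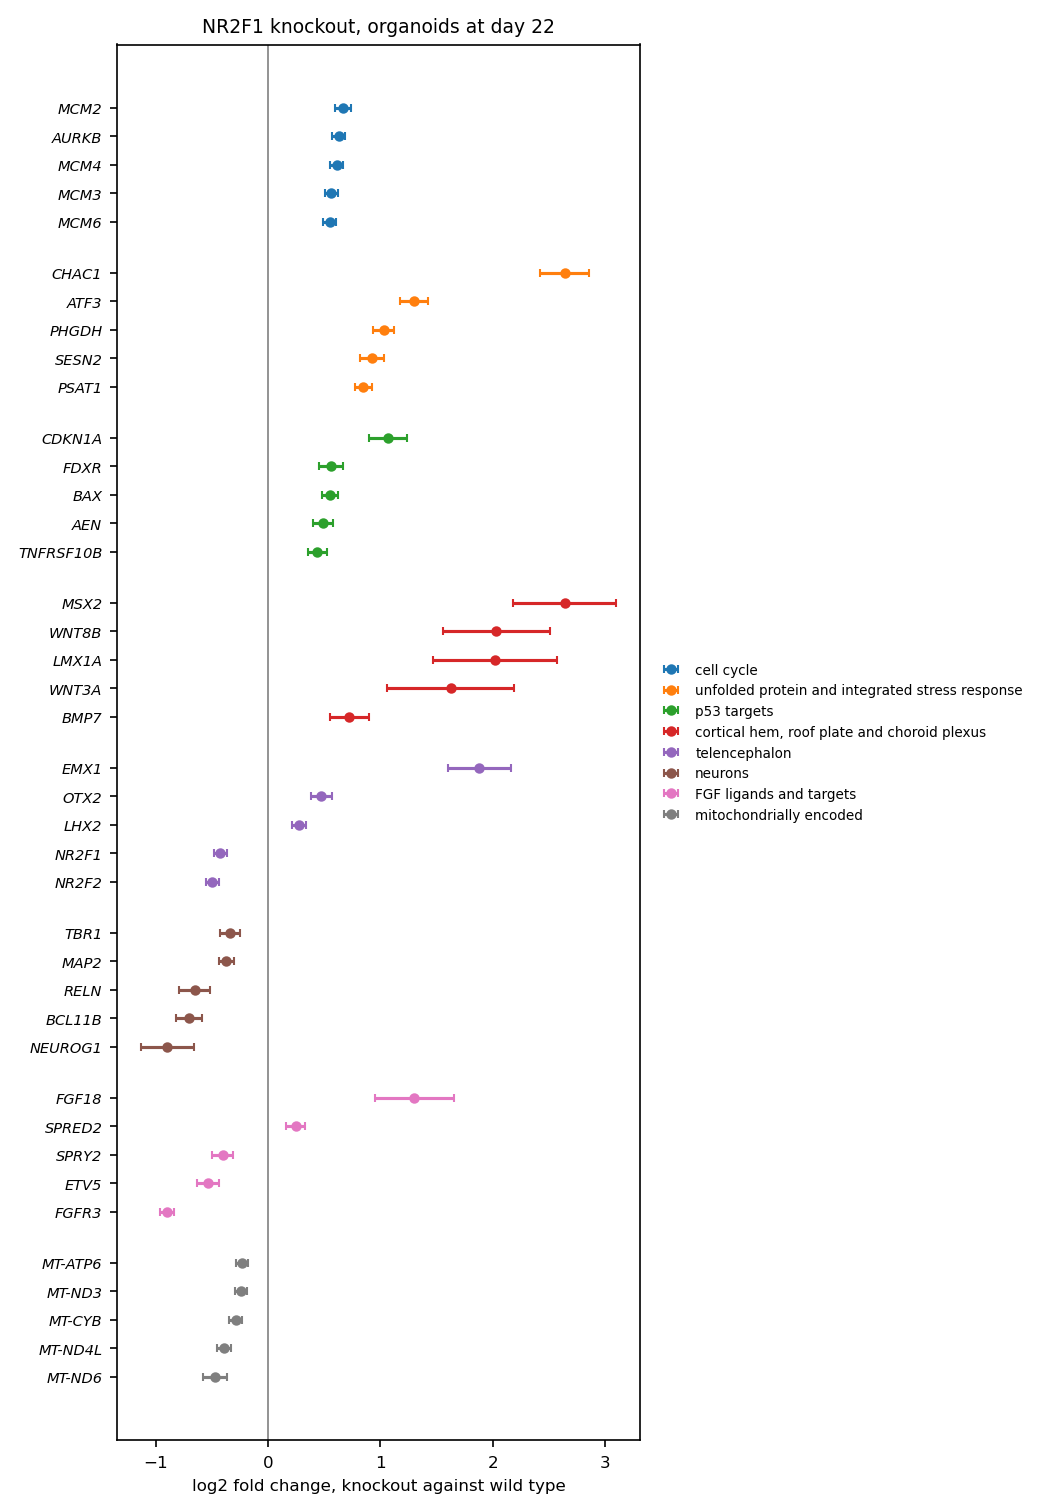
Log2 change of called members of selected fixed gene lists in NR2F1 knockout organoids against wild type at day 22 (n = 3 libraries each). Each point is a gene, placed on the horizontal axis by log2 change, with a standard error bar and a colour for its list. Only the members with the smallest adjusted p of each list, all under 0.05 over all genes, are drawn. Over the whole lists, drawn in part, all 21 cell cycle genes rose and 12 of 13 mitochondrially encoded genes fell. The share of reads in no gene also differed between the groups (16.6 to 19.0% against 23.5 to 29.7%).

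Other large rises were of CYP2S1 (2.75), the desmosome gene DSP (2.37), the serotonin receptor HTR2C (2.25) and STC2 (2.18). Large falls were of PI15 (-3.66, from 2.37 ± 0.902 to 0.182 ± 0.0386 CPM), the opioid receptor OPRK1 (-2.05), CDK15 (-2.01), SLITRK2 (-1.97), LYG2 (-1.80), OTOGL (-1.76) and the antisense transcripts KCNH7-AS1 (-1.99) and PLCE1-AS2 (-1.79). NR2F6, another member of the family, rose by 0.55, and NR2F1-AS1 was at -0.17 (adjusted p = 0.053). The 18 genes called with the share of reads in no gene in the model included DCT (2.98 without and 2.48 with the share), FGFR3 (-0.90 and -1.04), the neurotrophin receptor NTRK2 (-1.62 and -1.55) and the carbonic anhydrase CA2 (-1.18 and -1.21), which were chosen after their values were seen. NR2F1 itself was not among the 18. The groups did not overlap for 47.4% of genes, where chance gives 10%.

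Wild-type organoids at day 22 and day 8 were compared to describe the change with time; day and experiment cannot be told apart here. Neuronal genes rose, 20 of 20 tested, such as DCX (5.86), ELAVL4 (7.68) and the cytoskeletal regulator STMN2 (7.80), and pluripotency genes fell, 10 of 10, such as POU5F1 (-5.69) and LIN28A (-5.01). The forebrain factor FOXG1 rose from 6.14 ± 0.648 to 577 ± 20.9 CPM (6.55), and NR2F1 by 6.21. All 9 ventral forebrain genes rose (ASCL1 11.35, DLX2 7.90), as did all 13 cholesterol synthesis genes (HMGCS1 4.14, LDLR 3.82). Of 21314 genes 8554 rose and 8194 fell.

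Counts adjusted over the list alone equalled those over all genes for every list of this contrast. Camera called 11 lists, none of which passed with an estimated correlation (smallest adjusted p = 0.19). Besides the 4 above, they were epithelial genes (0 up and 12 down of 14; KRT18 -7.41), cell cycle (0 and 19 of 21; MCM3 -1.56), FGF (2 and 10 of 12; DUSP6 -4.09, FGFR3 5.74), diencephalon, midbrain and hindbrain (1 and 13 of 15; PAX2 -6.28), endothelium (1 and 6 of 7; KDR -7.83), mesenchyme (2 and 9 of 11; COL1A1 -6.30, VIM 3.55) and mitochondrially encoded genes (10 and 1 of 13; MT-ND5 1.51). The others, with numbers up and down, were telencephalon (11 and 6 of 18), radial glia (8 and 3 of 12; HES5 6.23), eye field (5 and 3 of 9; RAX -9.92), WNT (9 and 2 of 15; RSPO3 3.63), cortical hem (8 and 3 of 15; BMP6 3.86), Notch (8 and 6 of 16), NRF2 (5 and 8 of 17), DLX (5 and 2 of 7), MBNL targets (14 and 6 of 25; MAPT 4.40), hypoxia (7 and 9 of 18; VEGFA 2.51), p53 (8 and 4 of 15; CDKN1A 2.97), stress response (7 and 6 of 15; ATF4 1.90), interferon (2 and 8 of 11), immediate early (8 and 4 of 13; JUN 3.74), neural crest (3 and 6 of 9), placode (4 and 6 of 10), mesoderm (3 and 2 of 5) and endoderm (1 and 1 of 2).

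At 0 counts in every day 8 library, and so at least 19100-, 1710-, 1560-, 697- and 547-fold higher at day 22 against a floor of 3 counts over the group, were LINC00461, INSM1, GSX2, GJD2 and FAP. ZFP42, UGT3A1, SIX6 and APLNR were at 0 at day 22, at least 892-, 416-, 211- and 198-fold lower. Floors cover counting error only. DLX6-AS1 was at 224 ± 10.6 against 0.0281 ± 0.0277 CPM, DLX1 at 111 ± 14.6 against 0.0210 ± 0.0364 CPM and NSG2 at 108 ± 12.1 against 0.0189 ± 0.0164 CPM. PAMR1 (-11.65), VWF (-10.99), L1TD1 (-10.52) and CCBE1 (-10.19) fell. The groups did not overlap for 80.1% of genes, where chance gives 10%.

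Finally, the wild-type trophoblast cultures of sets A, B and C were compared to measure how far sets differ with no knockout, and 3930 of 17928 genes differed, 550 of them by more than 2-fold. COL3A1, a fibrillar collagen, was at 59.4 ± 4.15 CPM in set A, 25.5 ± 2.37 in set B and 19.7 ± 1.29 in set C, and the intermediate filament gene VIM at 10.2 ± 0.795, 3.79 ± 0.306 and 2.54 ± 0.0929 CPM. TNC, GABRP, KDR, NDNF, IGFBPL1, SHISA2, CDH3 and CPE, the others with the smallest p-values, were also highest in set A. Without wild-type replicate 1 of set B the count was 2559. The cultures of the sets are not told apart from the experiments they came from.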

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

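The model with the share of reads in no gene, its count of kept MBNL3 calls and the test of TWIST2 knockout replicate 3 were chosen after the result was seen. The groups of 3 libraries are too small for an outlier test.

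The NR2F1 knockout gave 6132 called genes at day 22, and its libraries had a lower share of reads in no gene (difference of means -8.07 points). Slopes on this share within the groups of the day 22 libraries predicted the sign of 85.6% of the called changes (correlation across genes 0.703, and genes are not independent replicates), so the share, or what moves it, may account for much of the pattern. Slopes within the day 8 groups predicted 64% of the signs, which leaves open whether the relation is a general one. With the share in the model 18 genes were called, all 18 among the 6132, and 83.0% of the 6132 kept their direction. Over the 6132 the median size of the log2 change went from 0.43 to 0.21 and its median standard error from 0.094 to 0.183. The loss of calls thus went with both smaller changes and larger standard errors. The share also separates the groups completely, and what this adds to the loss was not tested. The knockout and the state of the cultures or RNA that sets the share cannot be told apart for the genes that lost their call, and the loss of NR2F1 stays open and untested.

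The TWIST2 knockout gave 0 called genes, but 4192 with replicate 3 left out. Over all 18154 genes, the root mean square log2 distance from wild-type libraries was 0.856 of the largest of a wild-type library for replicate 3, and 1.29 and 1.52 for replicates 1 and 2. TWIST2 was at 56.9, 63.9 and 38.1 CPM in replicates 1 to 3, the last within wild type (27.9 to 39.6 CPM). Replicate 3 may thus be wild-type in its expression, though MBNL2 knockout replicate 1 was within the wild-type distances too (0.938). Slopes on the share of reads in no gene within the groups of sets A and C predicted the sign of 97.9% of the changes in replicates 1 and 2 (difference of means -5.24 points, correlation across genes 0.899, regression slope 2.18), so the share may contribute. The MBNL2 and MBNL3 knockout libraries also moved in the direction of these calls, by medians of 0.13 to 0.30. MBNL2 replicate 2 did so (0.23), though its share of 24.7%, above every wild type of the set, predicts the opposite. The genes were called against the same 3 wild-type libraries, so a movement shared by knockouts is expected in part. Another split of these 6 libraries called 3319 genes against 0 for the real one, which points to a structure that the groups do not explain. Whether replicate 3 carries the edit, and a difference between cultures, stay open.

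The MBNL3 knockout gave 1146 called genes while the share of reads in no gene differed by -1.18 points and overlapped. With the share in the model 95.7% of the genes stayed called in the same direction, and their median size of the log2 change went from 0.54 to 0.52 and its standard error from 0.114 to 0.107, which argues against the share as the whole cause. Against the wild type of sets A and C 98.7% of the called genes changed the same way (692 of them called). This argues against the wild type of set B as the only source of their direction. How far that wild type adds to their size stays open, since the same knockout libraries were used. Of the called genes 88.7% had the same sign in the MBNL2 knockout and 81.0% in the TWIST2 knockout. These knockouts share the wild type of set B, so a common control or a change shared by edited clones can give this. Slopes on the share within sets A and C predicted 73.2% of the signs, which decides nothing. In a regression across genes of the changes on those predicted the slope was 9.97 (correlation 0.732). The loss of MBNL3, a difference of edited clones from the parental line, and differences between clones stay open as hypotheses.

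With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 6132 and 1 for NR2F1, 1146 and 0 for MBNL3, 1837 and 0 for SIX3, 6 and 0 for HEY1, 0 and 0 for HOPX and DLX4, 14 and 0 for MAFF, and 1 and 0 for MBNL2, DLX5 and DLX6. Between knockouts they were 1 and 1 for DLX4 and DLX5, 1 and 0 for DLX4 and DLX6, 3 and 0 for DLX5 and DLX6, and 220 and 0 for MBNL2 and MBNL3. They were 16748 and 0 for day 22 against day 8. For transcript usage they were 30 and 26 for MBNL2, 61 and 31 for MBNL3, and 30 and 29 for TWIST2 by diffSpliceDGE, and 3 and 8, 69 and 4, and 1 and 27 by voom. Other splits thus gave nearly as many usage calls as the real one, or more, for MBNL2 and TWIST2.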

How the results depend on the processing

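The share of reads in no gene as a covariate, the 9 wild-type trophoblast libraries as controls, and voom for usage were chosen after the data were seen; the other alternatives were planned. For the changes below the cause was not tested, except where stated. RLE scaling kept every count within 1.5 times that reported. Salmon gene counts did so except for MBNL2 against MBNL3, with 417 genes.

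Without a filter on low counts, HEY1 had 305 called genes, HOPX 59, MAFF 664, MBNL2 270, TWIST2 577, DLX5 6, DLX6 22, DLX4 against DLX6 14, and MBNL2 against MBNL3 394, with 1 gene shared by DLX5 and DLX6 and 226 by MBNL2 and MBNL3. DESeq2 called 41 for HEY1, 1 for HOPX, 239 for MAFF, 52 for MBNL2, 2 for TWIST2, 2 for DLX4, 16 for DLX5, 80 for DLX6, 17 for DLX4 against DLX6 and 468 for MBNL2 against MBNL3, with 1 shared by DLX4 and DLX5, 9 by DLX5 and DLX6, and 43 by MBNL2 and MBNL3. Of the reported calls, DESeq2 also called 1103 for MBNL3, 1628 for SIX3 and 5182 for NR2F1. With only the libraries of the groups compared, which leaves the spread to fewer libraries, HEY1 had 449, HOPX 2, MAFF 3, MBNL2 496, MBNL3 2046, DLX5 74, DLX4 against DLX5 0, DLX5 against DLX6 1, MBNL2 against MBNL3 712, and 405 shared by MBNL2 and MBNL3. With all 36 trophoblast libraries in one model, MAFF had 0, MBNL3 1819, DLX4 5, DLX5 9, DLX6 36 and MBNL2 against MBNL3 632, with 1 shared by DLX4 and DLX5, 4 by DLX4 and DLX6, and 4 by DLX5 and DLX6.

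With the 9 wild-type trophoblast libraries as controls, HEY1 had 240, HOPX 179, MAFF 517, MBNL2 2, MBNL3 2538 (914 of the reported 1146 among them), TWIST2 1, DLX4 23, DLX5 88 and DLX6 75; differences between sets enter these counts. With the share of reads in no gene as a covariate, HEY1 had 522, HOPX 1, MAFF 175, DLX4 13, DLX5 2, SIX3 756 (693 of the reported 1837) and NR2F1 18. MBNL3 had 1326 then, with 1097 of the reported genes.

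For transcript usage in the MBNL2, MBNL3 and TWIST2 knockouts, a minimum share of 10% of the gene gave 17, 27 and 10 genes, and no minimum gave 131, 155 and 157. A gene-level F test gave 132 for MBNL3, and limma voom and diffSplice gave 3 for MBNL2 and 1 for TWIST2 (69 for MBNL3). Of the gene list calls, 79 as reported, an estimated inter-gene correlation left 0 and fry gave 17, while Salmon counts gave 80.

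Leaving out each library in turn gave a lowest and highest count of 1 and 6 for HEY1, 0 and 1 for HOPX, 0 and 326 for MAFF, 1 and 2 for MBNL2, 272 and 960 for MBNL3, 0 and 4192 for TWIST2, 0 and 0 for DLX4, 0 and 1 for DLX5, 1 and 1 for DLX6, 1070 and 2066 for SIX3, and 4221 and 5506 for NR2F1. It gave 0 and 1 for DLX4 against DLX5, 1 and 1085 for DLX4 against DLX6, 1 and 3 for DLX5 against DLX6, 62 and 142 for MBNL2 against MBNL3, 16298 and 17268 for day 22 against day 8, and 2559 and 5705 for the wild-type sets. Genes shared by MBNL2 and MBNL3 were 0 to 1 and by pairs of DLX knockouts 0 to 0. Usage counts were 14 to 40 for MBNL2, 24 to 65 for MBNL3 and 14 to 52 for TWIST2, and by voom 2 to 5, 29 to 61 and 0 to 42. The libraries that moved a count of edgeR by more than 1.5 times are named beside it in the report.

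Over all these settings 206 values of the counts stayed within 1.5 times the reported one and 112 moved. For the 435 pairs of a named gene and a comparison 4714 values were computed with the covariate and the 9 controls left aside: 4211 kept their direction and side of the threshold, 494 kept their direction but no longer passed, 9 kept it and newly passed, and 0 changed direction. Of these pairs 314 kept both throughout. List members entered the pairs only where they passed over all genes and were among the smallest adjusted p of their list. Not every list member named above is therefore covered. With the share of reads in no gene as a covariate 181 of 298 pairs kept both, 104 no longer passed, 1 newly passed and 12 changed direction. In NR2F1 3 of 102 kept both and 87 no longer passed, and the 12 were DSP (2.37 as reported and -0.17 with the share), KRT8 (2.19 and -1.51), WNT8B (2.03 and -0.47), LMX1A (2.02 and -1.81), WNT3A (1.63 and -2.66), KRT19 (1.37 and -0.73), IER3 (1.20 and -0.57), DHCR7 (0.41 and -0.20), THY1 (0.37 and -0.03), TALDO1 (0.29 and -0.11), IER2 (0.28 and -0.15) and SREBF2 (0.25 and -0.06), none called with the share. With the 9 wild-type libraries as controls 84 of 113 kept both, 26 no longer passed, 3 newly passed and 0 changed direction. In the self-test 43.3 to 59.7% of 1.5-fold changes were recovered, so at this number of libraries many changes of that size are missed.

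Whether equal wild-type numbers pair the cultures was checked from deviations from the group mean over 11910 genes. Day 8 and day 22 gave correlations across genes of -0.037, 0.102 and 0.066, sets A and B 0.064, 0.174 and 0.105, sets A and C 0.124, 0.155 and 0.008, and sets B and C 0.065, 0.291 and 0.028. In each of the 4 comparisons 2 of 3 cultures matched their own number best, but not every pair passed 0.1, so the numbers were not used as pairs. A replicate block gave 16847 genes for day 22 against day 8 and 4995 for the wild-type sets.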

Other observations

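The correlations with the share of reads in no gene and the comparisons of list members between the wild-type sets and of all knockouts together were chosen after the result was seen. The comparison of the wild-type sets and its draws of other splits were planned.

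Within groups of the 36 trophoblast libraries, the share of reads in no gene moved with the mean level of several gene lists. Both were taken as deviations from the group mean, and p-values came from 100000 permutations within groups. Of 22 lists 14 passed after adjustment by r, 13 with a negative and 1 with a positive correlation, and 8 of them also by rho. The epithelial junction and keratin list had r = -0.885 (permutation p = 3.0e-05, adjusted 0.00066) and rho = -0.856 (permutation p = 8.0e-05, adjusted 0.0018), with r of -0.983, -0.848 and -0.833 within sets A, B and C. The NRF2 list had r = -0.766 (adjusted permutation p = 0.0033) and rho = -0.741 (adjusted 0.0058), with -0.878, -0.836 and -0.515 within the sets. Cholesterol synthesis had r = -0.710 and rho = -0.684, and the stress response list r = -0.683 and rho = -0.597. The syncytiotrophoblast list had r = -0.640 (adjusted permutation p = 0.022) and rho = -0.499 (adjusted 0.0502, which does not pass), and the pluripotency list r = 0.478 (adjusted 0.022) and rho = 0.430 (adjusted 0.0502, which does not pass either). Without DLX6 knockout replicate 1 (35.5%) and TWIST2 knockout replicate 3 (23.1%), the libraries farthest from their groups, r was -0.852 for the epithelial list, -0.736 for NRF2, -0.625 for cholesterol synthesis, -0.545 for the stress response, -0.454 for syncytiotrophoblast and 0.358 for pluripotency.

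The wild-type cultures of the trophoblast sets differed in 3930 genes. Of 100 draws of splits of the 9 libraries, the real one included, 1 gave as many, and the highest other gave 1882. A division by chance is thus unlikely to account for the count, but 100 draws cannot exclude it. Of 26 syncytiotrophoblast genes 20 differed (23 adjusted over the list alone), with a median log2 difference of -0.41 for set B against set A and 0.05 for set C against set A. CGA was at 7408 ± 421, 4482 ± 1042 and 6830 ± 508 CPM in sets A, B and C, and FN1 at 360, 621 and 321 CPM. Of 15 mesenchyme and matrix genes 11 differed, with medians of -0.24 and -0.57, and of 11 amnion genes 8 differed, with medians of -0.00 and -0.59.

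The 9 trophoblast knockouts together were compared with the 9 wild-type libraries, within sets, to ask whether edited clones share a change. Of 19425 genes 56 were called, 17 higher and 39 lower, and with the share of reads in no gene in the model 201 were called, all 56 among them. AGFG2 was at -0.42 (adjusted p = 6.5e-07, lower in 9 of 9 knockouts), CX3CL1 at -0.62 (lower in 8 of 9) and AHNAK2 at 0.40 (higher in 9 of 9). With 1 group per set as the control in all 64 ways, 23 choices gave as many called genes, the real one included, and the highest other gave 3951 (median of the others 6). A change shared by edited clones may exist for single genes. Other choices have knockouts as controls, whose own changes enter, so they do not decide on the count of 56.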
